A study of Danio rerio with 2 samples.

How the data were processed

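The series holds 2 single-cell RNA libraries from zebrafish embryos at 24 hours post-fertilisation, a stage when the somites, brain regions and first blood cells are already formed. The control library came from wild-type embryos and the other library from embryos exposed to ionizing radiation (IR). Each group is 1 library. The design text mentions 30 pooled embryos without saying whether that number is per group or in total, and it gives neither the radiation dose nor the time between exposure and collection. Per the labels' protocols, cells were captured with the 10x Genomics 5' v2 chemistry at a target of 10000 cells and sequenced as paired ends.

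The deposited values were whole-number counts of unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule) per gene and barcode, with no normalization. The submitters' processing notes name FastQC, Cell Ranger 5.0.0, Seurat 4.3.0, R 4.2.2 and the genome build GRCz11, without saying which step each was used for. Per the file headers, the count matrices were written by Cell Ranger 6.0.0, which differs from the version in those notes. Both matrices list 25107 features and exactly 15000 barcodes, more than the 10000 cells targeted, and the rule by which 15000 barcodes were chosen is not given in the sources used here. Gene names and identifiers were taken from the deposited feature lists. The features carried 24424 distinct symbols, and the counts of features that share a symbol were summed. No genome of this build was used here, so no coordinates are given. Reads from near-identical families (haemoglobins, he1 proteases, keratins, crystallins) can be split between members, so values of single members of these families are uncertain.

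Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrial genes. This left 14979 control and 14955 IR-exposed barcodes. Of the barcodes left out, 21 in the control library and 44 in the IR-exposed library were over the mitochondrial limit and 1 in the IR-exposed library had too few genes. The doublet caller Scrublet, run in scanpy 1.11.5 with an expected rate of 0.06, called 0 doublets in either library, so it has not worked and doublets remain in the data. As an alternative, the 900 barcodes per library with the highest Scrublet scores were left out. Both libraries hold many barcodes of low depth. In the control library 7063 barcodes, and in the IR-exposed library 6876, had fewer than 1500 UMIs. Barcodes of at least 5000 UMIs, the low point of both UMI histograms, were therefore also analysed on their own.

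Barcodes of both libraries were clustered jointly, with no integration. Values were scaled to 10000 per barcode and log-transformed. From 2000 variable genes picked within each library, 30 principal components and 15 neighbours were computed, and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 38 clusters. The genes of the response lists, mitochondrial, ribosomal protein and haemoglobin genes were left out of the variable genes, so that clusters were not built from list genes. Genes compared outside the lists, he1.1 and he1.2 among them, were not left out. Clusters were named from 33 sets of cell type markers. A name was given only where at least 3 markers of a type were among the 50 leading genes, more than of any other type. Among the 10 leading genes, no other type could have more markers than the type named. Unnamed clusters are called by number. Named clusters were merged into classes, which gave 32 classes with the unnamed clusters counted, of which 15 had at least 200 barcodes in each library. The hatching gland-like class was not compared by share, since nearly all barcodes of its clusters 2 and 32 came from the IR-exposed library. The otic vesicle-like cluster was also led by the pancreatic hormone genes ins and sst2.

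For each gene, UMIs were summed over the kept barcodes of a library and divided by the library total, as CPM (counts scaled to the same total in both libraries). The ratio of IR-exposed over control CPM carries an exact conditional binomial 95% interval, and shares of barcodes carry exact Clopper-Pearson 95% intervals. These intervals cover counting error only. With 1 library per group no test between conditions was possible, and no p-value is given. Genes with at least 50 UMIs over both libraries entered the list comparisons, 17603 in all. For each of 18 gene lists, the median log2 ratio of the measured members was compared with the medians of 10000 random lists of the same size matched on mean expression. Its percentile among them describes these 2 libraries and is no test. The spread of a median over the list's members is given as a 95% order-statistic interval. A ratio against a library with 0 UMIs would be computed against a floor of 3 counts. Within classes, list members with at least 20 UMIs in the class were used. For values with equal class weights, also called class-standardised, class CPMs were averaged. The weight of a class, the same in both libraries, was its mean share of barcodes over both.

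The lists covered p53 targets, DNA repair and damage checkpoint, apoptosis machinery, S phase, G2 and M phase, antioxidant response, heat shock, unfolded protein and integrated stress response, immediate early genes, innate immunity and inflammation, glycolysis, the nuclear-encoded respiratory chain, hypoxia response, Notch and proneural genes, neuronal differentiation, lens, melanin pigment and extracellular matrix. They share 9 genes among them, of which baxa, bbc3, casp8 and pmaip1 are on both the p53 and the apoptosis list. Lists, markers, filters, the comparisons and the alternatives were fixed before the data were examined, except for the alternatives named as chosen later. The genes named were picked by size. Rule A took the 8 highest and 8 lowest class-standardised ratios among genes with at least 300 UMIs whose ratio lay on the same side of 1 in at least 75% of classes. Rule B took the 5 highest and 5 lowest whole-library ratios among genes with at least 300 UMIs. Genes without a standard symbol, mitochondrial genes and ribosomal protein genes were not ranked under rules A, B and C. Rule C took the 3 highest and 3 lowest ratios in each of the 6 largest classes. It used genes with at least 100 UMIs in the class and a CPM there of at least 0.25 times their highest class CPM. Rule D took the 2 most abundant and the 2 most different members of each list. Genes that these rules picked but that could not be described briefly are left out, and list members beyond rule D are named where a count of 5 or fewer or a list's own examples called for it, chosen after their values were seen. The results of 1 list member are not reported here.

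For the share of barcodes with cycling transcripts, each barcode was thinned to 1000 UMIs and counted as positive with at least 3 UMIs of the G2 and M phase list. The ratio and list steps were tested on simulated counts drawn from the real library sizes and means, with 200 genes altered. Simulated folds of 4, 2, 0.5 and 0.25 were recovered for the whole-library comparison as medians of 3.98, 2.00, 0.498 and 0.244, and for 17360 unaltered genes 95.5% of intervals covered the true ratio. A p53 list raised 1.5 times was recovered at 1.49, with its median at percentile 100. The 16 lists not altered as a whole had percentiles from 9.57 to 99.3. Of these, the apoptosis, immediate early and unfolded protein lists held genes raised with the p53 list. The range is therefore not that of unaltered lists alone, and a percentile inside it is a weak ground for setting a list apart. The remaining simulated lists differed by counting noise only. Percentiles of real lists, whose genes may shift together, can spread more widely. Alternatives covered the barcode filters, the barcodes with the most UMIs, scaling, class standardisation, cluster resolution and gene choice. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.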

Results

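The libraries were compared to ask how exposure to ionizing radiation relates to gene expression and cell composition in the zebrafish embryo at 24 hours post-fertilisation. The control library held 70922173 UMIs in 15000 barcodes and the IR-exposed library 73992291. After filtering, the median barcode had 1618 UMIs and 813 genes in the control library, and 1637 UMIs and 834 genes in the IR-exposed library. Barcodes of at least 5000 UMIs made up 24.2% of the control library (95% interval 23.6 to 24.9) and 21.5% of the IR-exposed library (20.9 to 22.2). They carried 73.7% and 73.4% of all UMIs. Each group is 1 library, so no difference reported here has a replicate check. Intervals of ratios and shares cover counting error only, and members' intervals of list medians cover the spread between genes only.

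**Figure D1:**
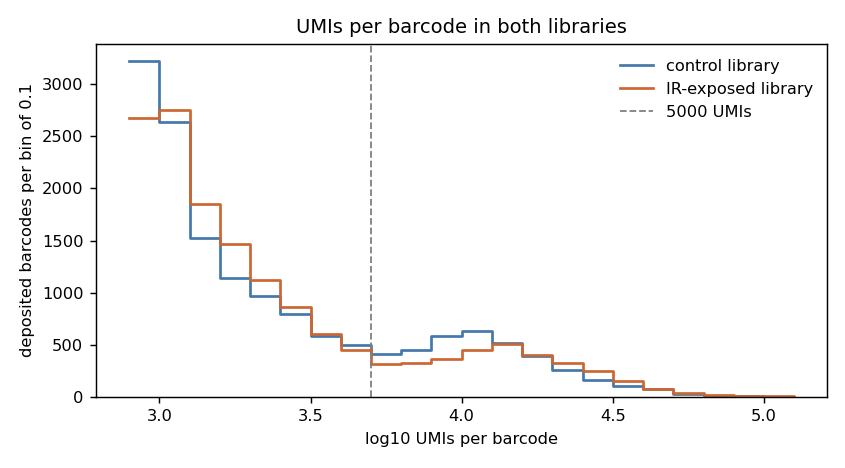
Number of deposited barcodes (vertical axis) by log10 UMIs per barcode (horizontal axis, bins of 0.1) in the control and the IR-exposed library. Both libraries have a low-depth group and a smaller group above the dashed line at 5000 UMIs.

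Several genes of the p53 pathway were far higher in the IR-exposed library. The transcript of mdm2 (ENSDARG00000033443), which encodes a ubiquitin ligase, was 6.77 times as abundant (95% interval 6.41 to 7.16; 1453 UMIs in control, 10262 in IR-exposed). The transcripts of rps27l, ccng1 and cdkn1a were 6.03, 4.02 and 5.35 times as abundant. Of these, cdkn1a encodes the cell cycle inhibitor p21, and ccng1 encodes cyclin G1.

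Of the 27 measured members of the p53 target list, 20 had a ratio above 1. The list median was a log2 ratio of 0.27, at percentile 100 of the random lists. The median of all measured genes was -0.11, and the p53 list lay 0.37 above it. The most different members included mdm2 at a log2 ratio of 2.76, phlda3 at 2.31 and casp8, an initiator caspase gene, at 2.14. The proapoptotic genes bbc3 and baxa followed with log2 ratios of 1.14 and 0.49. Other members lay on both sides of 1. The abundant btg2 had a log2 ratio of 0.05, whereas ppm1da, which encodes a phosphatase, and ei24 were lower at -0.55 and -0.59.

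The higher p53 target levels were found across cell types. In the 15 classes with at least 200 barcodes in each library, the list median was above 0 in all 15, from 0.33 in neuron-like to 0.85 in muscle progenitor-like barcodes. The members' interval lay above 0 in 12 of them. Each of mdm2, rps27l, cdkn1a, phlda3 and ccng1 was higher in the IR-exposed library in all 15 classes. The size varied. The log2 ratio of ccng1 was 0.64 in basal epidermis-like and 2.86 in neuron-like barcodes, and that of mdm2 ran from 1.92 in neuron-like to 3.51 in neural progenitor-like barcodes. Basal epidermis-like barcodes already had 929 CPM of ccng1 in the control library, against 297 CPM in neural progenitor-like barcodes.

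**Figure D2:**
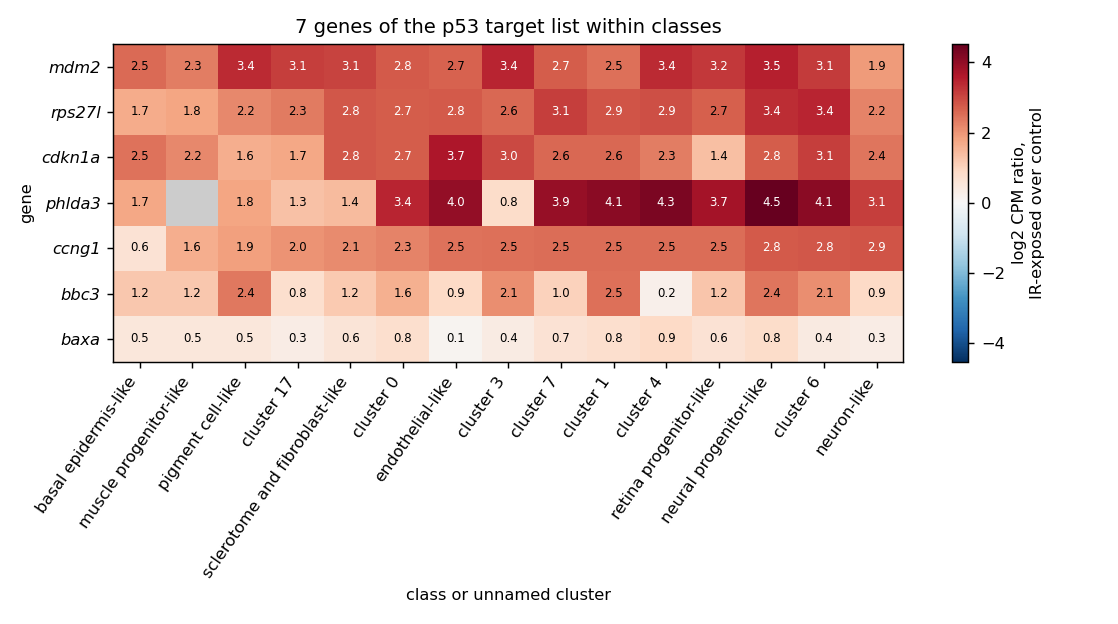
log2 ratio of CPM (colour and printed value), IR-exposed over control, for 7 genes of the p53 target list (vertical axis) in the 15 classes or unnamed clusters with at least 200 barcodes per library (horizontal axis, ordered by ccng1). Grey marks a gene with 3 UMIs or fewer in a library; every other cell is above 0, and ccng1 spans 0.64 to 2.86.

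Among the highest ratios outside the p53 list, some were spread over many barcodes and classes. The transcript of rspo1 (ENSDARG00000104340), encoding the secreted Wnt signalling enhancer R-spondin 1, had 29 UMIs in the control library and 1035 in the IR-exposed one, a ratio of 34.2 (23.7 to 51.4). It was detected in 649 IR-exposed barcodes. The ratio was 17.8 (12.2 to 26.8) for ghrh, encoding growth hormone-releasing hormone, and 16.4 (12.6 to 21.6) for RNF14, a ubiquitin ligase gene named as in the deposited feature list, where 2 features carry that name. The ratio for rbl2, a retinoblastoma family gene, was 7.63 (6.58 to 8.90), and that for the ubiquitin ligase gene lnx1 was 4.96 (4.40 to 5.61). The lower end held mpz, encoding myelin protein zero, with 706 UMIs in control and 174 in IR-exposed (0.236, 0.199 to 0.279). It also held the fatty acid desaturase gene fads2 at 0.273, bcl11ab at 0.297 and p2rx3a, encoding an ATP-gated channel of sensory neurons, at 0.313. Several other extreme ratios rested on few barcodes. Among the ranked genes with at least 300 UMIs over both libraries, the highest whole-library ratio was that of smtla, which encodes a pituitary hormone. It had 3 UMIs in the control library and 305 in the IR-exposed one, 57.7% of these in 1 of 20 barcodes. The hormone gene prl had 1078 UMIs in the IR-exposed library, 62.3% of them in 1 barcode, and the neutrophil lysozyme gene lyz had 3070 UMIs in the control library, 50.7% of them in 1 barcode.

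Inflammatory genes were higher in the IR-exposed library as a group. Of 25 measured members of the innate immune list, 20 had a ratio above 1, and the median log2 ratio was 0.39 (0.49 above that of all genes; percentile 100). The interferon-stimulated gene isg15 had 92 UMIs in control and 1467 in IR-exposed, a ratio of 15.3 (12.4 to 19.1), and was higher in all 17 classes where it was measured. The chemokine gene cxcl8a had a ratio of 2.81, the collagenase gene mmp13a 2.23 and the cytokine gene il1b 1.85. Few of the 15 large classes measured these 3 genes. The log2 ratio of cxcl8a was above 0 in 3 of 4 classes, from -2.36 in sclerotome-like barcodes to 5.71 in cluster 0. That of il1b was above 0 in 1 of 2 classes, and mmp13a was measured in 1 class, where it was higher. The inhibitor gene nfkbiab was lower at 0.701 (0.679 to 0.725). The ratio of il6, 4.47, rested on 70 IR-exposed UMIs, 95.7% of them in 1 barcode. Within classes the members' interval of this list lay above 0 in 1 class and below 0 in 1 class of 15.

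Genes of energy metabolism were slightly higher. Of 37 measured genes of the nuclear-encoded respiratory chain, 35 had a ratio above 1. Their median log2 ratio was 0.26, at percentile 100, and within classes it ranged from 0.13 to 0.31 and lay above 0 in all 15. The most abundant member, atp5f1b, a subunit of ATP synthase, had a log2 ratio of 0.23. Cytochrome c, encoded by cycsb and listed under both the respiratory chain and apoptosis, was at 0.58. Glycolysis genes had a median of 0.23 (19 of 22 above 1, percentile 99.99), with pgam2 at 0.65, eno3 at 0.51 and aldoab at 0.50. All of these 3 are abundant in muscle, and fast muscle markers had a median of 0.58 (17 of 18 above 1). With equal class weights the glycolysis median was 0.14, and its members' intervals lay above 0 in 2 of the 15 classes. The hypoxia response list had a median of -0.28 (4 of 18 above 1, percentile 4.29), which is -0.17 relative to all genes and inside the range of the random lists, with the stress gene ddit4 at -0.83.

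The remaining stress lists had medians between 0.02 and 0.19 above that of all genes. The antioxidant list, the highest of them and just above the range of its random lists, had a median log2 ratio of 0.09 (17 of 26 above 1, percentile 98.3), with the haem oxygenase gene hmox1a at 0.84 and the quinone reductase gene nqo1 at 0.61. Among barcodes of at least 5000 UMIs its median was 0.045, at percentile 94.1. Both of these percentiles lay inside the range that the simulated lists covered. The heat shock list had a median of 0.05 (percentile 87.4), with hspb1 at 0.53. The unfolded protein and integrated stress response list had a median of 0.02 (percentile 83.0), and the immediate early list 0.01 (percentile 58.2), with egr1 at -0.52. The apoptosis list had a median of 0.03 (15 of 29 above 1, percentile 95.8), and its most different members, casp8 and bbc3, are also on the p53 list. The DNA repair list had a median of -0.09, or 0.02 relative to all genes (13 of 42 above 1, percentile 54.8), with apex1 at -0.05 and parp1 at -0.09. The extracellular matrix list had a median of 0.00 (18 of 33 above 1, percentile 82.8), within which the actinodin genes and2 and and1, components of fin fold fibres, stood at 1.90 and 0.81.

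**Figure D3:**
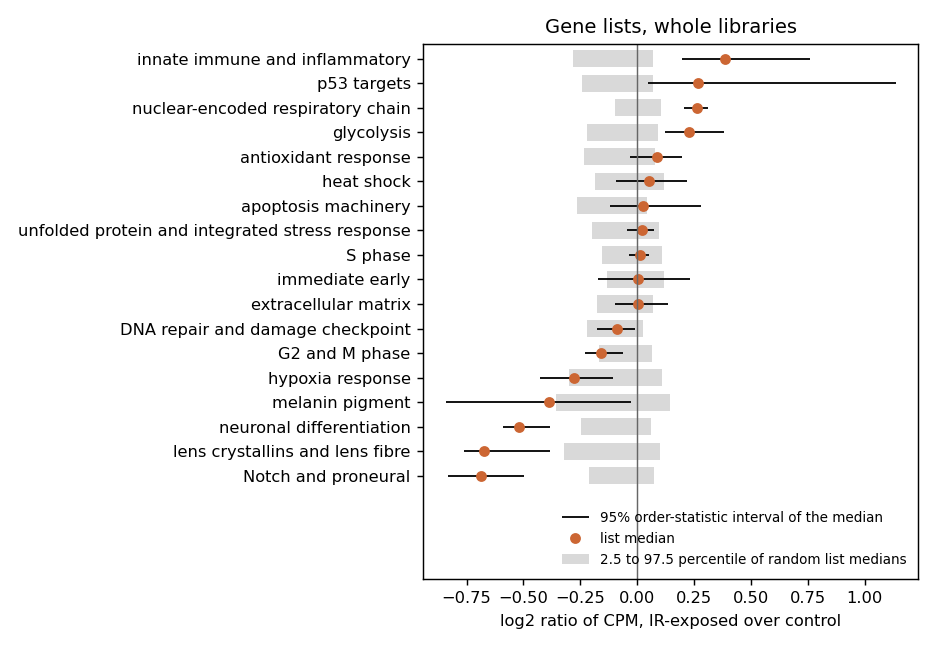
Median log2 CPM ratio, IR-exposed over control (horizontal axis), of the 18 gene lists (vertical axis) over whole libraries, with the order-statistic interval over members (line) and the central range of matched random lists (grey bar). The p53, innate immune, respiratory chain, glycolysis and antioxidant medians lie above the grey range, and the Notch and proneural, neuronal, lens and melanin medians lie below it.

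Genes of neurogenesis and neuronal differentiation were lower in the IR-exposed library. Of 27 measured Notch and proneural genes 25 had a ratio below 1, and their median log2 ratio was -0.69 (0.58 below that of all genes, percentile 0). The Delta ligand genes dla, dlb and dld had log2 ratios of -1.05, -0.74 and -1.31, and the neuronal transcription factor gene insm1b -1.10. With equal class weights dla, dlb and dld stood at -0.61, -0.15 and -0.94. Exceptions were her9, a hairy-related repressor gene, at a log2 ratio of 0.58, and her2 at 0.12, or -0.06 among barcodes of at least 5000 UMIs. Of 25 neuronal genes 24 had a ratio below 1, with a median of -0.52 (percentile 0). The RNA-binding protein genes elavl3 and nova2 stood at -0.78 and -0.77.

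Within classes both lists were mostly lower too, although free RNA, which was not removed, may contribute outside neural classes. The Notch and proneural median was below 0 in all 15 classes, from -0.69 in retina progenitor-like barcodes to -0.22 in cluster 6, and the members' interval lay below 0 in 11. With each class given the same weight in both libraries the median was -0.32. The neuronal list gave -0.18 on that scale, but 0.24 with equal cluster shares among barcodes of at least 5000 UMIs. Its median was above 0 in 1 of 15 classes, neuron-like barcodes, at 0.14 (18 of 25 genes above 1), and the members' interval lay below 0 in 5. At that depth the Notch and proneural median in neuron-like barcodes was 0.12, against -0.23 over all kept barcodes, and the neuronal median was 0.07 in muscle progenitor-like and 0.10 in sclerotome-like barcodes, against -0.73 and -0.45. The gene her9 was higher in all 15 classes.

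Lens and pigment genes were lower too. The lens list had a median of -0.67 (2 of 21 above 1, percentile 0). The crystallin genes crybb1 and cryba4 stood at -0.51 and -0.49, and foxe3, a lens epithelium transcription factor gene, was higher at 0.79. Among barcodes of at least 5000 UMIs the lens median was -0.38, at percentile 2.28. No class of the main clustering was named as lens. Of 2419 control UMIs of crybb1, 776 lay in barcodes of that depth, which carried 73.7% of all control UMIs. Within classes the lens median was above 0 in 3 of 14 and lowest in basal epidermis-like barcodes, at -1.54. Free RNA, which was not removed, may therefore contribute to the lens values. All 11 measured melanin genes had a ratio below 1 (median -0.39, percentile 1.65), with the melanosome gene pmela at -0.60 and slc24a5 at -0.98. With equal class weights the melanin median was -0.17. In pigment cell-like barcodes it was -0.15 (members' interval -0.58 to 0.09, 3 of 11 above 1).

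Cell cycle genes differed by class more than over whole libraries. The G2 and M phase list had a median log2 ratio of -0.16 (7 of 39 above 1, percentile 3.2), which is -0.05 relative to all genes. The proliferation marker mki67 stood at -0.34 and the phosphatase gene cdc25b at -0.60. The S phase list had a median of 0.01 (percentile 69.8) over whole libraries, but its median was above 0 in all 15 classes, and pcna, the replication clamp, was higher in each of them. In retina progenitor-like and neural progenitor-like barcodes the G2 and M median was -0.40 and -0.16. It was 0.81 in pigment cell-like, 0.76 in muscle progenitor-like, 0.39 in basal epidermis-like and 0.33 in neuron-like barcodes, the last of which turned to -0.31 at a finer cluster resolution. In neuron-like barcodes the extracellular matrix list was higher too, at 0.68 (21 of 24 above 1, percentile 100), so transcripts typical of other cell types differed there as well.

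After thinning to 1000 UMIs, 57.4% of control barcodes (56.5 to 58.3) and 59.4% of IR-exposed barcodes (58.6 to 60.3) carried at least 3 UMIs of the G2 and M list. Before thinning the shares were 79.7% and 81.5%. Thinning left out 3219 control and 2670 IR-exposed barcodes that were too shallow. Among barcodes of at least 5000 UMIs the order was the other way, 44.4% against 43.5%, with overlapping intervals. In retina progenitor-like barcodes the share was 68.0% (63.8 to 72.1) in control and 57.5% (52.1 to 62.8) in IR-exposed, and in pigment cell-like barcodes 25.2% (19.8 to 31.2) and 36.4% (30 to 43.1). Neuron-like barcodes, which largely consist of postmitotic cells, had 20.7% and 24.1%, and free RNA was not removed from either value. Haemoglobin transcripts, which mark red blood cells, reached 798 CPM in the other classes of the control library and 979 CPM in those of the IR-exposed library. Among barcodes of at least 5000 UMIs in these classes the order was the other way, with a ratio of IR-exposed over control CPM of 0.493 (0.480 to 0.506). Classes differed in this. Over all kept barcodes, fast muscle-like barcodes had 2108 CPM in control and 137 CPM in IR-exposed, whereas cluster 0 had 3055 and 5752 CPM. The ratio among the deeper barcodes may therefore rest on few classes, which was not tested.

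The IR-exposed library held a smaller share of neural cells and a larger share of epidermal cells. Among barcodes of at least 5000 UMIs, clustered without hatching gland genes, neural progenitor-like barcodes were 11.7% of the control and 7.17% of the IR-exposed library, a ratio of 0.614 (0.521 to 0.722). Neuron-like barcodes had a ratio of 0.618 (0.487 to 0.781). Periderm-like barcodes, the outer skin layer, had a ratio of 2.01 (1.51 to 2.69), and basal epidermis-like barcodes 1.45 (1.18 to 1.78). Over all kept barcodes in the main clustering these ratios were 0.635, 0.562, 1.83 and 1.26. Transcripts of the hatching gland proteases he1.1 and he1.2 differed as well, with 69.8 CPM in control and 230 CPM in IR-exposed barcodes of at least 5000 UMIs outside the hatching gland-like class.

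Unnamed cluster 0, a low-depth cluster led by histone genes, held 31.3% of control and 32.3% of IR-exposed barcodes, and cluster 1, led by fabp7a and stmn1a, 18.1% and 12.2%. An unnamed cluster led by the neurogenic genes neurod4, dlb and insm1a held 308 control and 111 IR-exposed barcodes, a share ratio of 0.361 (0.288 to 0.450). Without hatching gland genes, the clusters with these among their leading genes held 504 and 216 barcodes, or 175 and 71 of at least 5000 UMIs. The main clustering put 1731 IR-exposed barcodes into hatching gland-like clusters 2 and 32, which lowers the main share of any other class they belong to. Retina progenitor-like barcodes had a ratio of 0.686 (0.597 to 0.787) over all kept barcodes and 0.891 (0.755 to 1.05) among those of at least 5000 UMIs. Erythroid-like barcodes had ratios of 1.14 (0.901 to 1.43) and 1.41 (1.09 to 1.84). Fast muscle-like barcodes had ratios of 1.32 and 1.70, but 0.941 at a finer resolution and 0.971 with clusters made from control barcodes. For muscle progenitor-like, otic vesicle-like, pigment cell-like and endothelial-like barcodes the interval among barcodes of at least 5000 UMIs included 1, and sclerotome-like barcodes lay on different sides of 1 in the main clustering (0.822) and at that depth (1.12).

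**Figure D4:**
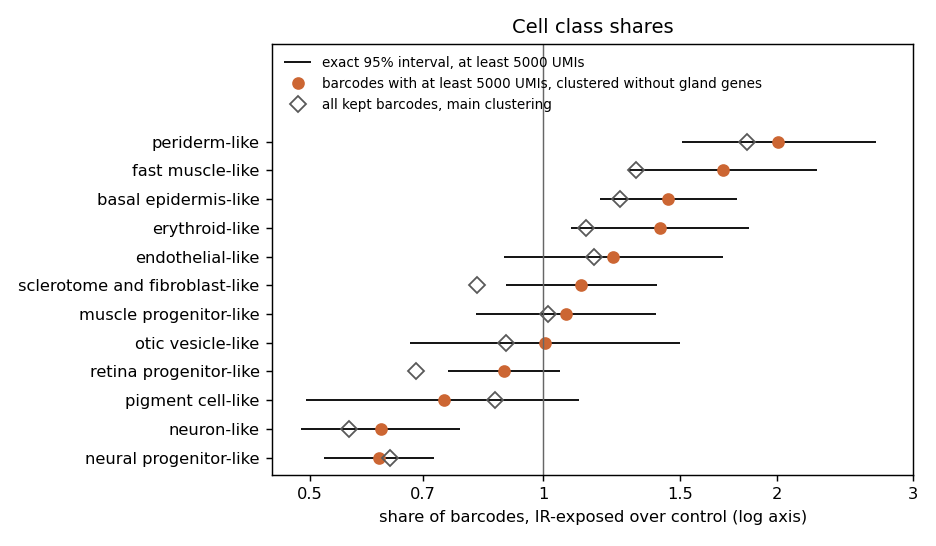
Share of barcodes in 12 classes (vertical axis), IR-exposed over control on a log axis (horizontal), for barcodes of at least 5000 UMIs with exact 95% intervals (filled points and lines) and for all kept barcodes (open diamonds). Neural progenitor-like and neuron-like ratios lie below 1 and periderm-like and basal epidermis-like ratios above 1 on both scales.

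Within single classes, the highest ratios again included p53 targets. In neural progenitor-like barcodes rbl2 had 5 control and 181 IR-exposed UMIs (50.7, 21.3 to 158), rspo1 had 5 and 142, and igf2a, encoding an insulin-like growth factor, 9 and 179. The Wnt antagonist gene sfrp1a was lower there at 0.287 (0.231 to 0.354), and smad3b, encoding a TGF-beta signal transducer, at 0.296. In cluster 4, led by fgfr1b, the ratios of phlda3, mdm2 and fsta, encoding the activin antagonist follistatin, were 19.3, 10.4 and 6.91. The median barcode of that cluster had 2579 UMIs in control and 2435 in IR-exposed. In neuron-like barcodes the transcription factor genes scrt1b, lbx2 and fezf1 were lower, with ratios of 0.0620 (0.0166 to 0.163), 0.148 and 0.163. These genes were detected in few barcodes, 33, 26 and 31 of 624 in control and 4, 5 and 7 of 350 in IR-exposed. Among the ranked genes with at least 100 UMIs in that class, the neuropeptide genes penka and pnoca had the highest ratios. However, 95.7% and 90% of their IR-exposed UMIs were in 1 barcode. In cluster 3, led by the mesenchymal genes grem2b and prrx1a, the steroid synthesis gene star had 264 IR-exposed UMIs, 100% of them in 1 barcode, and dlx3b was lower at 0.342 (0.289 to 0.403).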

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

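All tests in this part were chosen after the results they address had been seen.

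Clusters 2 and 32, led by the hatching gland protease genes he1.1 and he1.2, stood out as a signal outside the class comparison, which left them out: they held 1731 IR-exposed but 110 control barcodes. Cluster 35, the cluster with the most he1 transcripts per UMI, held 17 IR-exposed and 14 control barcodes, a share ratio of 1.22 (0.564 to 2.67). This argues against a rise of barcodes like those of cluster 35 as large as that of clusters 2 and 32. It cannot decide whether clusters 2 and 32 hold gland cells themselves, since the clustering had set them apart from cluster 35. For barcodes of at least 5000 UMIs outside the gland class, gland RNA spread evenly through the suspension is argued against. Of these barcodes, 72.5% in the IR-exposed library but 50.4% in the control library had no he1 UMI. A candidate explanation at that depth is gland RNA in a part of the IR-exposed droplets whatever cell they hold. The share of barcodes above 1000 CPM of he1 was higher in the IR-exposed library in 100% of 31 clusters. Doublets, which remain in the data, were not examined as a source. The hatching gland-like class itself had a median of 1946.5 UMIs per IR-exposed barcode. Comparisons among barcodes of at least 5000 UMIs therefore do not settle what clusters 2 and 32 hold. Whether the gland RNA in that part of the droplets reflects the exposure, the dissociation or the capture stays open with 1 library per group.

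The lower neurogenic and neuronal lists were weighed against 3 technical or compositional explanations. Low-depth barcodes as the cause are argued against by the medians among barcodes of at least 5000 UMIs, of which the less negative one, for the neuronal list, was -0.51 (members' interval -0.61 to -0.45). A general delay of development could not be decided: of 6 sets of markers of differentiated non-neural types whose interval excluded 0, 33.3% were lower (lens at -0.49 and pigment cell at -0.48), while fast muscle at 0.58, slow muscle, periderm and erythroid were higher, and the shares of cell types move all of them too. Fewer neurogenic cells alone could neither be excluded nor retained: with equal cluster shares at that depth, the Notch and proneural median was -0.21 (-0.43 to -0.02) and the neuronal median 0.24 (0.09 to 0.28), against -0.05 for all genes, while the main classes over all kept barcodes gave -0.18 for the neuronal list. Whether the lower lists lie in the share of cells, in their content or in free RNA stays open, as does an effect of the exposure.

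Between named classes, 3 lists lay on opposite sides of 0 with members' intervals that excluded 0; the innate immune and unfolded protein lists did so only against unnamed cluster 17. These differences between classes were not tested. The G2 and M phase median was 0.81 in pigment cell-like and -0.40 in retina progenitor-like barcodes. The neuronal differentiation median was 0.14 (percentile 98.6) in neuron-like and -0.45 in retina progenitor-like barcodes, the latter inside the range of its random lists (percentile 4.73), whose median there was -0.21. The immediate early median was 0.17 in neuron-like barcodes, inside the range of its random lists (percentile 97.4), and -0.15 in basal epidermis-like barcodes (percentile 0).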

How the results depend on the processing

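Results with at least 5000 UMIs, without the highest Scrublet scores and without hatching gland genes were chosen after seeing the data. The cause of the differences below was not tested, unless stated. No paired analysis was possible because each group is 1 library and no result comes from a test. For the same reason leaving out a replicate was not possible. Shares under all deposited barcodes were not run, and keeping doublet calls tests nothing, since no barcode was called. A share has no value where an alternative left the class unnamed. With at least 1000 UMIs and 500 genes, all 50 results stayed within their intervals, as did all 48 without the highest Scrublet scores, all 38 over all deposited barcodes and all 38 without mitochondrial, ribosomal and haemoglobin genes in the total.

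With equal class weights 22 of 38 whole-library results stayed within their intervals and 1 was counted as reversed. With means over barcodes 26 of 38 stayed. At resolution 2 of the clustering 42 results stayed, 7 moved outside their intervals and 3 were counted as reversed. At least 5000 UMIs left 74 results within their intervals, among them values near 0 that changed sign. At that depth 14 results moved outside their intervals and 2 were counted as reversed. The p53, innate immune and glycolysis medians stayed within their intervals under all alternatives run. Cluster 0, with median depths of 1008 and 1067 UMIs, stayed unnamed.

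Values below are log2 ratios unless given as percentages, with the main value in parentheses. With equal class weights, which by construction removes differences of class share, the medians were 0.087 for DNA repair (-0.09), -0.0043 for G2 and M phase (-0.16), -0.32 for Notch and proneural genes (-0.69), 0.17 for S phase (0.01) and -0.18 for neuronal genes (-0.52). Centred on the median of all genes, which adds 0.11, they were 0.017 for DNA repair, -0.051 for G2 and M phase, 0.12 for S phase, 0.37 for the respiratory chain (0.26) and 0.13 for the unfolded protein response (0.02). As means over barcodes they were -0.025 for G2 and M phase, 0.081 for S phase and -0.38 for neuronal genes, and as ratios of summed CPM 0.056 for S phase and -0.62 for neuronal genes. With at least 5000 UMIs the lens median was -0.38 (-0.67).

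For shares, resolution 2 gave -0.088 for fast muscle-like (0.40), 0.036 for sclerotome-like (-0.28) and -1.22 for neural progenitor-like barcodes (-0.66), and resolution 0.5 gave -0.23 for retina progenitor-like (-0.54). With at least 5000 UMIs shares were 0.55 for basal epidermis-like (0.33), 0.77 for fast muscle-like, -0.60 for neuron-like (-0.83), -0.30 for retina progenitor-like and 0.088 for sclerotome-like barcodes. With gland genes left out as well, they were 0.77 for fast muscle-like, -0.17 for retina progenitor-like and 0.16 for sclerotome-like barcodes. Leaving out gland genes alone gave -0.61 for neuron-like barcodes, and clusters made from control barcodes gave -0.042 for fast muscle-like and -1.07 for neuron-like. The 10000 barcodes with the most UMIs gave 0.0070 for endothelial-like (0.22) and -0.27 for retina progenitor-like barcodes, all variable genes gave -0.41 for neural progenitor-like, and the 5% mitochondrial limit gave 0.10 for fast muscle-like and -0.028 for sclerotome-like barcodes.

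Within classes, resolution 2 moved the G2 and M phase median to 1.12 in muscle progenitor-like (0.76), -0.31 in neuron-like (0.33), 0.56 in pigment cell-like (0.81) and 0.34 in sclerotome-like barcodes (0.19), and the neuronal median to -1.28 in muscle progenitor-like (-0.73), -0.79 in neural progenitor-like (-0.41) and -0.11 in sclerotome-like barcodes (-0.45). Resolution 0.5 moved G2 and M phase to 0.18 in basal epidermis-like (0.39) and the neuronal list to -0.26 in retina progenitor-like barcodes (-0.45). With at least 5000 UMIs, G2 and M phase was 0.57 in endothelial-like (0.28) and 0.0059 in neuron-like barcodes, and the neuronal list 0.074 in muscle progenitor-like and 0.10 in sclerotome-like barcodes. The cycling share was 84.3% in control and 86.4% in IR-exposed barcodes with at least 1 UMI, and 65.2% and 68.4% after thinning to 2000 UMIs, settings that change the threshold itself.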

Other observations

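Marker sets of other tissues, which were fixed to name classes and not as a comparison, also differed between the libraries. The periderm markers had a median log2 ratio of 0.55 (15 of 16 above 1), the fast muscle markers 0.58 (17 of 18) and the erythroid markers 0.22 (16 of 18). Markers of the motor neuron and oligodendrocyte lineage had a median of -0.43 (2 of 12 above 1), those of peripheral sensory neurons -0.47 (0 of 15) and those of the lateral line -0.35 (1 of 9). The endothelial, notochord and sclerotome markers had medians of -0.04, -0.05 and -0.00. Of these sets, several share genes with the neuronal, lens and pigment lists.

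The control level of p53 targets differed between classes. The transcript of phlda3 had 68.7 CPM in cluster 3 and 61.6 CPM in sclerotome-like barcodes of the control library, against 5.52 CPM in neural progenitor-like barcodes. In the IR-exposed library the values were 123, 167 and 127 CPM. For ccng1 the control level was 929 CPM in basal epidermis-like and 111 CPM in neuron-like barcodes, and the IR-exposed level was 1449 and 804 CPM.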
